A study of Mus musculus with 2 samples.

How the data were processed

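Poly(A) RNA of RAW264.7 cells was sequenced as paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols, in 2 libraries, 1 labelled SFRS8 siRNA and 1 labelled negative control. Groups were taken from the treatment labels. The submitters' processing notes name HISAT2 2.0 and StringTie 1.3.0. The genome build, the annotation and the strandedness of the library are not given in the sources used here. All 24034 gene identifiers were found in GENCODE vM21 (GRCm38), and 21651 (90.1%) had identical coordinates there, so this annotation was used for coordinates, transcript sequences and gene types.

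The deposited FPKM values, per the file headers, are normalised for transcript length and library size by the authors, and they summed to 455893 in the siRNA-labelled and 471516 in the control library. The deposited counts, per the file headers, are whole numbers, but low values piled up on multiples of 4, so they were treated as estimated counts derived from coverage in which 1 read pair gives about 4 counts. Of counts from 1 to 20, 45.1% and 42.7% were multiples of 4. Dividing by 4 gave the approximate number of read pairs. Intervals for ratios of counts were made on counts divided by 4, conditional on the sum of both libraries, with exact Clopper-Pearson limits at the 95% level. They cover counting error only, since reads without molecular identifiers are not independent molecules. Where the control was at 0, a lower bound of the fold was computed against a floor of 3 read pairs (12 counts) per gene. Each column was matched to its library by name, and 0 columns of values were left unmatched. FPKM and counts of the same library had a Spearman rho across genes of 0.960 and 0.966, against 0.912 for siRNA-labelled FPKM and control counts.

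Before the data were examined, the measure was set as the difference of log2(FPKM + 1), siRNA-labelled minus control, over genes with a mean of at least 1 FPKM. The pseudocount of 1 understates the difference of low genes. With 1 library per group no test between conditions was possible. Genes were counted by a rule of size, at least 2-fold on that scale. No count test was run. The 36 gene lists were also fixed beforehand, and each median was placed among 10000 random lists of equal size drawn from 20 bins of mean expression. Lists with fewer than 5 measured members got no percentile. The names fixed beforehand were Sfswap, the 10 highest and 10 lowest genes with a mean of at least 5 FPKM (leaving out predicted-gene symbols and symbols ending in Rik or ps), and from each list the 4 members with the largest differences and the 2 most abundant. The text gives a selection of the genes this rule names, and an item among them is withheld and not reported here. Other genes were named after their values were seen. These include Myl3, Myh6, Tnni3, Cox6a2, Fabp3, Hbb-bs, Fos, Nfatc1, Acp5 and the separate protein-coding genes. Duplicated symbols were represented by the more abundant gene. GO and KEGG terms in the deposited table with 10 to 200 measured genes were placed in the same way. GO terms were not used here for 1873 genes.

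Several steps were added after the data were examined. A gene was called separate when less than 25% of its longest transcript matched another gene (blastn 2.17.0, at least 98% identity over at least 100 nt) and it overlapped no gene of the table on the same strand. Differences were adjusted for GC content by lowess with a span of 0.3. Marker lists of heart muscle, fast skeletal muscle, red blood cells, liver, brain, kidney, vascular endothelium and fibroblasts were written, and their summed counts compared. The sums were taken both over all members and over members under 1 FPKM in the control library, the second version being added once the first had been seen. Alternatives were other pseudocounts, filters, fold limits and scalings, unmatched random lists, counts scaled to the library total, removal of sharing genes and of heart muscle markers, and the GC adjustment.

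The procedure was tested on simulated data drawn from the mean of both libraries with counting noise alone. The rule of size recovered 67% of 2.5-fold and 98.0% of 4-fold simulated genes, and 5.25% of unchanged random lists fell outside the central 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.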

Results

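Messenger RNA of RAW264.7 cells, a mouse monocyte/macrophage line, was sequenced in 2 libraries. One library was labelled SFRS8 siRNA and the other negative control, and both sample titles carried a 5 d mark whose starting point the labels did not explain. SFRS8 is an older name of Sfswap, a regulator of alternative splicing. The deposited table listed 24034 genes, each with an FPKM value (fragments normalised for transcript length and library size) and an estimated count per library. The counts summed to 55411201 in the siRNA-labelled library and to 54847367 in the control library, and 19518 and 18630 genes were above 0. There was 1 library per group, so no difference below has a replicate check and no p-value was computed. Differences are the siRNA-labelled minus the control value of log2(FPKM + 1), and intervals are 95% exact limits of the ratio of counts that cover counting error only.

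Sfswap, the gene the siRNA was labelled as targeting, was not lower in the siRNA-labelled library. Sfswap (ENSMUSG00000029439, chromosome 5, 129501221 to 129571384, plus strand) stood at 3.38 FPKM there and at 2.92 FPKM in the control library, from 1664 and 1423 counts. The difference was 0.16 and the ratio of counts per total was 1.16, with an interval that ended at 1.34 and began just above 1. The median difference over all genes with a mean of at least 1 FPKM was 0.11, so Sfswap was close to a typical gene. Since the target was not lower, every direction below is that of the library labelled SFRS8 siRNA relative to the library labelled negative control. None is that of a measured loss of Sfswap. Sfswap overlaps Gm42979 on the same strand, which had 29 against 30 counts, and the summed counts per total of both genes differed by 0.21 on the log2 scale. A whole-gene value does not resolve individual isoforms of Sfswap or the protein.

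Heart muscle genes were among those highest in the siRNA-labelled library, and copies of ribosomal protein genes were among those lowest. Of 10214 genes with a mean of at least 1 FPKM, 121 were at least 2-fold higher and 80 at least 2-fold lower in the siRNA-labelled library, together 1.97%. Simulated counting noise alone carried 24 of 10009 unchanged genes past the same limit. The median difference over all genes was 0.11, and 66.9% of genes were above 0. Among the 10 named genes with the highest differences were Mb (myoglobin, the oxygen-binding protein of muscle), Actc1 (cardiac actin), Myl2 (the ventricular myosin light chain) and Tnnc1 (the troponin C of heart and slow muscle). Actc1 stood at 18.0 FPKM against 0 and Myl2 at 14.7 FPKM against 0, at least 147-fold and 145-fold higher when the control was set at a floor of 12 counts. Mb stood at 21.9 FPKM against 0.10 FPKM, but 37.0% of its longest transcript is also found in another gene. Tnnc1 stood at 9.11 against 1.56 FPKM.

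The other 6 of these 10 genes were Epo, Pdxp, Ak4, Rpl10-ps1, Hnrnpf and Rpl13-ps6. Ak4, a mitochondrial adenylate kinase, stood at 12.1 FPKM against 2.06 FPKM, a ratio of counts of 5.87 (4.92 to 7.05). Hnrnpf, a splicing regulator, stood at 98.7 against 22.8 FPKM, but 74.4% of its longest transcript is shared with other genes. Epo (erythropoietin) was listed at 15.7 FPKM against 0, but it overlaps Gnb2 on the same strand. Pdxp shares 45.1% of its transcript with Gm49510. The 10 genes with the lowest differences were Rpl22-ps1, Rpl30-ps8, Rpl10-ps3, Rpl35a-ps2, mt-Th, mt-Ts2, Eno1b, mt-Tl2, Rpl15-ps3 and Rnu3b2. They comprised 5 copies of ribosomal protein genes (4 of them annotated as pseudogenes and Rpl10-ps3 as protein-coding), 3 mitochondrial transfer RNAs, a small nucleolar RNA gene and Eno1b, an enolase copy at 68.1 against 538 FPKM that shares 92.2% of its transcript.

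Genes whose reads can be assigned to another gene were frequent on both sides. Genes that shared sequence with another gene or overlapped one on the same strand made up 71 of the 121 higher genes (58.7%) and 67 of the 80 lower genes (83.8%), against 30.6% of the genes under 2-fold. Pseudogenes made up 23 of the higher genes (19.0%) and 44 of the lower genes (55%), against 9.07% of the genes under 2-fold. Without sharing or overlapping genes, a restriction chosen after the values were seen, 50 genes were higher and 13 lower. Ifitm2, an interferon-induced membrane protein, had 8349 counts against 26693, while the overlapping Gm45717 had 15834 against 0; the summed counts per total differed by -0.16 on the log2 scale.

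Separate protein-coding genes past 2-fold were mostly higher in the siRNA-labelled library, with 45 higher and 4 lower. The genes named next were chosen after their values were seen. Besides the heart muscle genes, the higher side held Klf2 (a transcription factor that restrains macrophage activation), Armc10, Zfp740, Pttg1ip, Hmgcs1 (an early enzyme of cholesterol synthesis) and Rhob. Klf2 stood at 11.4 against 2.92 FPKM, a ratio of counts of 3.91 (3.06 to 5.05), and Armc10 at 12.5 against 3.57 FPKM (3.48, 2.95 to 4.11). Hmgcs1 stood at 10.4 against 4.05 FPKM (2.56, 2.23 to 2.94). On the lower side were Pip5k1c (a phosphoinositide kinase), with 5.16 against 12.7 FPKM and a ratio of 0.41 (0.36 to 0.45), and Cipc, 2610001J05Rik and Tnfaip1.

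**Figure D1:**
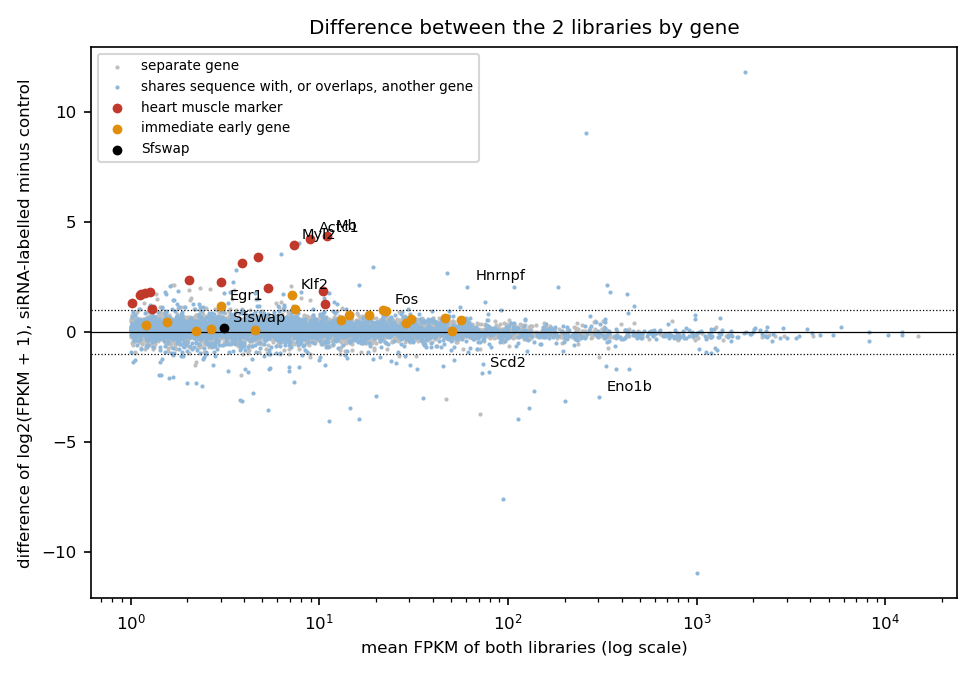
Difference of log2(FPKM + 1), siRNA-labelled minus control, against the mean FPKM of the 2 libraries on a log scale, with each point a gene with a mean of at least 1 FPKM and dotted lines at 2-fold. Sfswap sits at 0.16, heart muscle markers lie above 0, and most points beyond the dotted lines share sequence with, or overlap, another gene.

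Transcripts of contractile heart muscle were present in the siRNA-labelled library at levels near or below 22 FPKM and were near 0 in the control library for most markers, with Cox6a2, Fabp3 and Tnnc1 as the exceptions above 1 FPKM. Of 34 heart muscle markers, listed after the data were examined, 33 had counts and all 33 were higher in the siRNA-labelled library. Their summed counts were 17764 against 943, a ratio of 18.6 (16.3 to 21.3), and 38.4 (31.5 to 47.2) over the 31 markers under 1 FPKM in the control. Myh6 (a heavy chain of heart myosin) stood at 7.81 against 0.0069 FPKM, Myl3 at 9.52 against 0 FPKM and Tnni3 (cardiac troponin I) at 5.68 against 0.36 FPKM. Markers of fast skeletal muscle held 1099 against 1251 counts, a ratio of 0.87 (0.74 to 1.03), or 63 against 52 counts (1.20, 0.55 to 2.75) without the member above 1 FPKM in the control. Red blood cell genes held 423 against 6 counts, with Hbb-bs, a beta globin, at 3.39 FPKM against 0. Leaving the heart muscle markers out lowered the number of higher genes from 121 to 105 and left 80 lower.

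**Figure D2:**
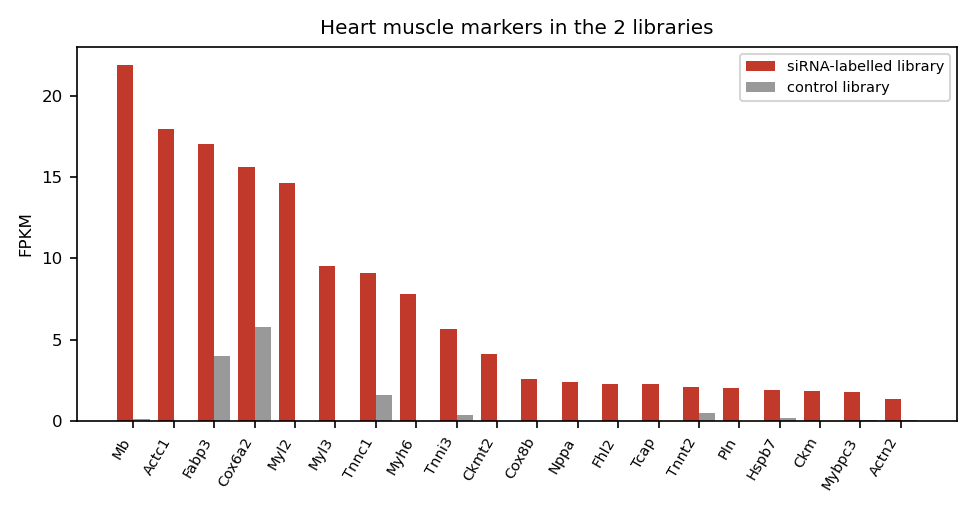
FPKM of the 20 most abundant heart muscle markers in each library, 1 bar per library and gene. Mb reaches 21.9 FPKM in the siRNA-labelled library against 0.10 FPKM in the control library, and Cox6a2 and Fabp3 have the highest control values, 5.80 and 3.98 FPKM.

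Gene lists fixed before the data were examined were compared with 10000 random lists of the same size and matched mean expression. Of 36 lists, 31 had at least 5 measured members, of which 7 had a median above and 2 a median below the central 95% of random lists; 1.55 lists would lie outside by chance if lists were independent. The percentiles describe these 2 libraries. Beside every list that follows, the heart muscle (17764 against 943 counts), red blood cell (423 against 6) and fibroblast markers (670 against 107) were higher in the siRNA-labelled library. Across genes, the difference followed the GC content of the transcript (Spearman rho -0.46 across genes, which are not independent replicates), with a median of 0.34 among genes of at most 42.1% GC (the lowest of 10 equal bins) and -0.03 among those of at least 57.9% GC (the highest bin). A median adjusted for this trend, an alternative chosen after the data were examined, is therefore given for the lists that stood apart. With it, 5 lists were above and 5 below the range, of which 5 and 2 were on the same side without it.

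Immediate early genes, the transcription factors and feedback regulators that respond first to a stimulus, were higher in the siRNA-labelled library. All 18 measured members had differences above 0, 4 of them at least 2-fold, and the median of 0.56 was above all 10000 random lists. The 4 were Klf2, Egr1 at 4.59 against 1.46 FPKM, Btg2 at 10.4 against 4.46 FPKM and Zfp36, which destabilises cytokine mRNAs, at 29.4 against 14.2 FPKM. The ratio of counts of Fos was 2.02 (1.82 to 2.24), while Atf3 differed little, with 52.0 against 49.6 FPKM (1.05, 0.98 to 1.12). The median was 0.64 after adjustment for GC content. The heart muscle and red blood cell genes were higher in the same library.

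Genes of mitosis were higher in the siRNA-labelled library by smaller amounts. Of 23 measured members of the G2/M and mitosis list, 22 were above 0 and none reached 2-fold on the log2(FPKM + 1) scale. The median was 0.39, above all 10000 random lists, and 0.31 after adjustment for GC content. Ttk, a spindle checkpoint kinase, stood at 2.94 against 1.42 FPKM (ratio of counts 2.07, 1.64 to 2.64), Kif11, a spindle motor, at 1.90 against 0.79 FPKM and Bub1 at 6.55 against 3.85 FPKM. The most abundant members differed less, with Cdc20 at 70.4 against 66.5 FPKM and Ccnb2 at 51.3 against 46.0 FPKM. Genes of G1/S and DNA replication had a median of 0.19, at percentile 95.2, with 19 of 23 members above 0. After adjustment for GC content that median was 0.09, at percentile 39.45. Histone genes that are mostly replication-dependent had a median of 0.39 over 8 measured members, at percentile 99.5, and of 0.49 after adjustment for GC content, but were inside the range in counts scaled to the library total (percentile 95.6). Hist1h1b, a linker histone, had 199 against 16 counts and Hist2h2ac 115 against 35 counts, so these rest on few reads, and transcripts of this class mostly lack the poly(A) tail used to select the RNA.

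Among genes of the splicing machinery, the hnRNP genes, which encode RNA-binding proteins that often oppose exon inclusion, were higher in the siRNA-labelled library. Their median was 0.31, above all 10000 random lists, with 23 of 24 members above 0, and it was 0.23 after adjustment for GC content. Hnrnpab stood at 99.5 against 56.7 FPKM, Hnrnpd at 6.47 against 4.02 FPKM and Hnrnpa1 at 213 against 178 FPKM, and Hnrnpf was the member at least 2-fold higher. Hnrnpab and Hnrnpa1 share 30.63% and 30.95% of their longest transcripts with other genes. Without sharing or overlapping genes the median was 0.32. The SR and SR-related splicing factors had a median of 0.25 with 26 of 27 members above 0, at percentile 96.9, inside the central range; with no minimum on FPKM (97.9) and against unmatched lists (98.7) it was above. Srsf5 stood at 12.9 against 7.26 FPKM, Clk1, a kinase of SR proteins, from 2002 against 1046 counts and Srsf1 at 3.73 against 2.02 FPKM. The core spliceosome did not stand apart, with a median of 0.01 over 34 members, although Snrnp70 stood at 35.7 against 21.2 FPKM. Host genes of small nucleolar RNAs had a median of 0.20 at percentile 93.1.

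Osteoclast genes did not stand apart, while repressors of osteoclast differentiation, the fate RAW264.7 cells can take under RANKL, were somewhat higher in the siRNA-labelled library, in which the heart muscle, red blood cell and fibroblast markers were also higher. The osteoclast list had a median of 0.05 over 13 members, none past 1.5-fold. Its master factor Nfatc1 stood at 7.64 against 7.33 FPKM, Acp5 (tartrate-resistant acid phosphatase) at 27.5 against 29.4 FPKM, Tnfrsf11a (the RANK receptor) at 5.84 against 4.69 FPKM and Mmp9 at 7.37 against 10.2 FPKM. The repressor list had a median of 0.35 at percentile 98.6, and 0.28 at percentile 98.3 after adjustment for GC content. In it, 9 of 10 members were above 0, with Id2 at 7.92 against 4.46 FPKM, Id1 at 34.2 against 23.2 FPKM and Irf8 at 12.2 against 13.6 FPKM. Its percentile was 95.7 without sharing or overlapping genes.

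The medians of macrophage and immune gene lists were inside the range of random lists, and that of a list of matrix, protease and integrin genes was below it. Macrophage identity genes had a median of -0.01, with Lyz2 (lysozyme) at 1129859 against 1251570 counts, Cd68 at 947 against 1067 FPKM and Cebpb, a myeloid transcription factor, at 20.8 against 11.1 FPKM. Inflammatory cytokines and mediators had a median of 0.03, with Tnf at 58.4 against 43.1 FPKM, Nos2 at 64.6 against 70.2 FPKM and Csf3 at 2.55 against 5.85 FPKM. Chemokines and receptors had a median of 0.00, which became -0.12 at percentile 0.23, below the range, after adjustment for GC content. Medians were 0.05 for NF-kB pathway and feedback genes and 0.14 for toll-like receptor and nucleic acid sensing genes. Interferon-stimulated genes had a median of 0.14 at percentile 76.2, with Rtp4 at 4.02 against 1.92 FPKM and Bst2 at 651 against 684 FPKM. Antigen presentation genes had a median of -0.02, with Cd74, the invariant chain, at 353 against 444 FPKM, and scavenger and phagocytic receptors of 0.07. The matrix, protease and integrin list had a median of -0.10 at percentile 1.4, with 8 of 12 members below 0, and of -0.09 at percentile 0.45 after adjustment for GC content. Itgb7 stood at 20.2 against 28.4 FPKM and Itgb2 at 141 against 162 FPKM, while Itga4 stood at 9.37 against 6.40 FPKM and Spp1 (osteopontin) at 6249 against 5410 FPKM. With no minimum on FPKM the percentile of this list was 59.4.

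Compared with genes of like abundance, cytosolic ribosomal protein genes were slightly lower in the siRNA-labelled library, and mitochondrially encoded genes slightly higher. Across genes the difference fell with mean FPKM (Spearman rho -0.22), and the matched random lists of both had medians of -0.09. The median difference over all genes was 0.11, close to the mitochondrial median below. The ribosomal protein list had a median of -0.15 at percentile 0.745, with 64 of 75 members below 0, and at a mean of at least 5 FPKM it was at percentile 4.63, inside the range. Rplp1, which shares 99.4% of its longest transcript with other genes, stood at 7104 against 9360 FPKM and Rps15 at 3850 against 4407 FPKM. The 13 mitochondrially encoded genes had a median of 0.10 at percentile 99.6, or 45.5 against unmatched lists, with mt-Nd1 at 377 against 273 FPKM and mt-Cytb at 533 against 395 FPKM. After adjustment for GC content the ribosomal median was -0.13, below the central range, and the mitochondrial median was -0.17 at percentile 1.79, on the other side. Nuclear-encoded respiratory chain genes had a median of -0.06 at percentile 28.0, or 0.01 against unmatched lists.

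Among stress, metabolic and survival lists, the p53 targets had a median above the range. It was 0.27 at percentile 98.8, with 13 of 19 members above 0, but 0.14 at percentile 75.1 after adjustment for GC content and at percentile 62.2 at a mean of at least 5 FPKM. Btg2 and Sesn1 (4.03 against 2.10 FPKM) were higher, Pmaip1 (Noxa, which promotes cell death) stood at 8.63 against 14.2 FPKM and Cdkn1a (the cell cycle inhibitor p21) at 165 against 173 FPKM. Apoptosis regulators had a median of 0.19, with Mcl1 at 70.8 against 48.9 FPKM. Heat shock genes had a median of 0.10, ATF4 and unfolded protein response genes of 0.09 and NRF2 targets of 0.07. In these lists Hspa5 (the chaperone BiP) stood at 339 against 238 FPKM, Atf4 at 162 against 227 FPKM and Srxn1 (sulfiredoxin) at 9.61 against 5.42 FPKM. Glycolysis and hypoxia genes had a median of -0.07 at percentile 4.01, with Aldoa (aldolase) at 1202 against 1563 FPKM. The list was below the range at a mean of at least 5 FPKM (percentile 1.01), against unmatched lists (0.21) and after adjustment for GC content (1.87). Without sharing or overlapping genes it was inside the range, with a median of 0.002 at percentile 13.79. Cholesterol synthesis genes had a median of 0.06, LXR and lipid handling genes of 0.01, and lysosome and V-ATPase genes of 0.02. Scd2, a fatty acid desaturase that overlaps another gene on the same strand, stood at 30.5 against 115 FPKM.

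**Figure D3:**
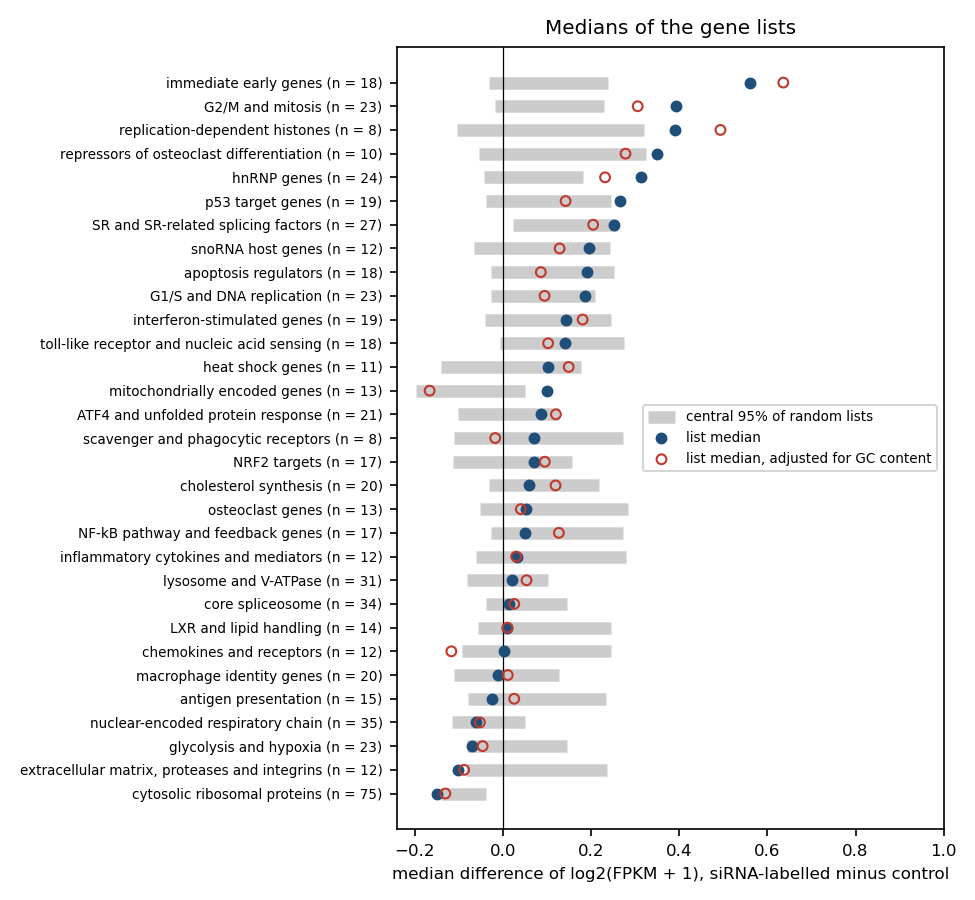
Median difference of log2(FPKM + 1), siRNA-labelled minus control, of the 31 gene lists (filled points), with the central 95% of 10000 random lists matched on mean expression (grey bars) and the median after adjustment for GC content (open points; the bars are those of the unadjusted values). Among the filled points, immediate early genes lie farthest to the right at 0.56 and cytosolic ribosomal proteins farthest to the left at -0.15.

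The 5 remaining fixed lists, mostly of other cell types, had fewer than 5 members measured at 1 FPKM and were compared by their summed counts. Fibroblast and osteoblast markers held 940 counts in the siRNA-labelled library against 410 in the control, a ratio of 2.27 (1.80 to 2.91). Lymphocyte markers held 8656 against 9527 counts, a ratio of 0.90 (0.85 to 0.95), nearly all from Ighm. Markers of granulocytes, mast cells and dendritic cells had a ratio of 1.19 (0.80 to 1.72), epithelial and endothelial markers of 1.48 (0.96 to 2.33), and markers of alternative macrophage activation of 1.01 (0.89 to 1.16).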

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

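The marker lists below, the tests on shared reads, red blood cells and markers low in the control library, the mitochondrial comparison, the GC adjustment of the immediate early genes and the exchange of labels were chosen after the results were seen. Markers of heart muscle, red blood cells and fibroblasts, which RAW264.7 cells do not represent, held more counts in the library labelled SFRS8 siRNA than in the control library. Heart muscle markers held 17764 counts against 943, red blood cell markers 423 against 6, fibroblast markers 670 against 107 (ratio 6.20, 4.09 to 9.62) and vascular endothelium markers 7962 against 7072. Liver markers held 70 against 24 counts (2.89, 1.13 to 9.14), brain markers 7449 against 6338 (1.16, 1.09 to 1.25) and kidney markers 0 in both, while fast skeletal muscle markers held 1099 against 1251 (0.87, 0.74 to 1.03). All 12 brain markers had counts in the control library. The brain and vascular endothelium sums were thus largely present there already.

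The heart muscle genes may come from heart tissue RNA or reads that entered the siRNA-labelled library, or from a muscle programme in the cells. A muscle programme alone would not account for the red blood cell genes, higher by a ratio of 69.8 (14.2 to 439). That ratio rests on 6 control counts, below the floor of 12. The test was chosen after the values were seen and does not decide where the heart muscle genes come from. Reads shared with other genes are argued against because 18.8% of the 16 measured heart markers share sequence. The endothelium test of a heart source was set beforehand at a ratio below 1.5 as the bound against it, and its value of 1.11 (1.04 to 1.19) met that bound, but members the control cells already express held 97.8% of the control counts (Fabp4 alone 88.2%) and would hide a small share. Over the 10 members under 1 FPKM in the control the ratio was 1.87 (1.25 to 2.80), which leaves a heart source open. A source of many tissues is also open. Its test was set beforehand at a ratio of 2, and the median of the liver and brain ratios, 2.02, lay just above that bound. Over 33 liver, brain and kidney members low in the control the ratio was 1.78 (1.48 to 2.14), below the bound. The outcome thus depends on the members chosen. Brain members held 1267 of the 1337 counts of these 33 members in the siRNA-labelled library. Liver markers held 70 against 24 counts and kidney markers 0 in both libraries. For heart muscle markers the ratio was 38.4 (31.5 to 47.2) over members low in the control and 18.6 over all members. Choosing members by a low control value can raise a ratio, and the heart list was written after the data were examined. The larger heart ratio therefore does not decide between these sources.

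Genes low in GC content were higher in the siRNA-labelled library, and a bias of library preparation or sequencing is a candidate explanation, since the trend was also present within the ribosomal protein genes (rho -0.38, bootstrap 95% limits -0.56 to -0.18). Whether it acts alike on mitochondrial transcripts is open, as their median lay -0.25 from that of nuclear genes in the lowest of 10 bins of GC, with limits of -0.29 to 0.00. The trend is argued against as the whole cause of 3 higher lists, whose adjusted medians stayed high, with rounded percentiles of 100 for immediate early genes, 100 for mitotic genes and 99.97 for hnRNP genes. Heart RNA as the source of the immediate early genes was not told apart from a response of the cells by the comparison set for it. These genes were higher by 139 FPKM in sum and the heart markers by 136 FPKM, a ratio of 1.02 (0.95 to 1.10). The heart sum depends on which markers were listed, so this ratio does not decide the question. A response to the siRNA treatment stays open and untested, since each group had 1 library.

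Sfswap was not lower in the siRNA-labelled library, and a failed or transient knockdown, or a knockdown of isoforms or protein not seen in a gene total, may underlie this but was not tested. An exchange of the labels of an effective knockdown is argued against, because Sfswap would then be at least 2-fold higher in the siRNA-labelled library, and the ratio was 1.16 with an upper limit of 1.34. A decrease hidden by the GC trend is argued against by an adjusted difference of 0.26. Reads shared with another gene are argued against by a shared 0% of the longest Sfswap transcript, and the overlapping Gm42979 held 29 against 30 counts, too few to hide a 2-fold decrease.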

How the results depend on the processing

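Alternatives with counts scaled to the library total, separate genes, heart markers left out or GC adjustment were chosen after the data were examined. The Sfswap difference stayed above 0 in all alternatives run. The numbers of higher and lower genes were 232 and 134 with a pseudocount of 0.1, 47 and 50 at a mean of at least 5 FPKM, 501 and 223 at 1.5-fold, and 50 and 13 without sharing or overlapping genes. Higher genes outnumbered lower ones in every alternative run except at 5 FPKM.

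For the list medians, repressors of osteoclast differentiation moved inside the central range with a pseudocount of 0.1 (percentile 97.2), at 5 FPKM (97.2) and over separate genes (95.7). At 5 FPKM the p53 targets were at 62.2 and ribosomal proteins at 4.63. The matrix, protease and integrin list was at 59.4 without a filter, with a median of 0.03. Mitochondrially encoded genes were at 45.5 against unmatched lists and at 1.79 after GC adjustment, and p53 targets at 75.1. Lists that moved outside were SR factors with no filter (97.9) and against unmatched lists (98.7), glycolysis and hypoxia at 5 FPKM (1.01), against unmatched lists (0.21) and after GC adjustment (1.87), chemokines after GC adjustment (0.23) and the respiratory chain against unmatched lists (0.01). Over separate genes, glycolysis and hypoxia stayed inside at 13.79. Histones were at 95.6 in counts scaled to the library total. The cause of these moves was not tested, beyond the construction of each alternative. Immediate early, mitotic and hnRNP lists stayed above the central range in every alternative run. Lists with too few members gave no value in 1 case at 5 FPKM and in 4 cases over separate genes. No paired analysis was possible because each group held 1 library. Depth limits genes of a few read pairs, such as most histone genes.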

Other observations

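All values in this part come from exploratory comparisons of annotation terms, and the genes named were picked by the size of their difference within each term. Of 1635 terms, 149 had a median above and 38 below the central 95% of random lists, where 40.9 would be expected on each side by chance if terms were independent, and 124 and 55 after adjustment for GC content. Without adjustment for GC content, cardiac muscle contraction had the highest excess over random lists. Its median was 0.65 over 15 genes, 7 of them at least 2-fold higher in the siRNA-labelled library, and 0.42 after adjustment. Its members with the largest differences, Actc1, Myl2, Myl3 and Tnni3, were below 1 FPKM in the control. They passed the filter on mean FPKM only through the siRNA-labelled library. Such genes can enter on the higher side only, which can raise the median of this term. Nucleosome followed, with a median of 0.57 over 49 genes, 44 of them above 0 and 12 at least 2-fold higher. After adjustment the nucleosome median was 0.62, above that of cardiac muscle contraction. The nucleosome members with the largest differences were Hist1h1b, Hist2h3c1 (266 against 6 counts), Hist1h4n (428 against 129 counts) and Hist1h2bb (174 against 41 counts). Histone copies share sequence with each other.

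Kinetochore assembly, a step of chromosome attachment, had a median of 0.48 over 11 genes and 0.26 after adjustment for GC content. Pogz stood at 1.88 against 0.67 FPKM and Cenph at 4.17 against 2.51 FPKM, while Cenpx, another of its members, stood at 42.5 against 73.1 FPKM. At the other end, cell-matrix adhesion had a median of -0.21 over 10 genes at percentile 0.04, and of -0.13 at percentile 0.14 after adjustment for GC content. In it, Itgb4 (an integrin subunit of epithelial anchorage) stood at 1.22 against 2.24 FPKM and Itgb7 at 20.2 against 28.4 FPKM.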
